A study of Arabidopsis thaliana with 12 samples.

How the data were processed

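Poly(A)-selected RNA was sequenced from samples labelled as shoots of Arabidopsis thaliana seedlings at 3 days post germination, all of the genotype clv3 epfl1 epfl2 epfl4 epfl6, per the labels. Root markers in mock, with PRP3 at 2170 ± 463 and CASP1 at 1260 ± 197, go against a harvest free of root tissue, and the labels do not say whether roots were removed. There are 4 groups of 3 biological replicates: mock, EPFL6, cycloheximide (CHX) and CHX plus EPFL6. Each replicate was 10 seedlings in 1 ml of liquid medium, so the 12 libraries were treated as separate biological samples. EPFL6 was added as 8.7 µl of a 10 µM solution, which computes to 86.2 nM in the medium, and mock samples received the same volume of buffer. Cycloheximide was used at 10 µM and given 10 minutes before EPFL6 or buffer. The labels do not give the time between the addition of EPFL6 and collection.

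Per the submitters' processing notes, the tools were STAR 2.7.6a, featureCounts 2.0.0 and DESeq2 1.26.0 on the TAIR10 genome. The deposited values are a scaled read signal per gene: reads divided by 1 size factor per library. This was read off the values themselves, since each column holds whole multiples of its smallest value. After multiplication by the factor, 100% of the values lay within 1e-06 of a whole number, and the factors equalled the median-of-ratios factors computed from the recovered reads. The notes give neither the counting mode nor the strand setting, so reads of overlapping or antisense genes can be shared. AT4G31610 and AT4G31615 overlap on chromosome 4, for example. The file lists 26702 genes, each with reads in at least 3 libraries, and 23863 of them are protein coding. Locus tags of the RefSeq TAIR10.1 annotation matched 26514 genes, and the 188 without a match are organelle genes.

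Recovered depth was 51.4 ± 4.74 M reads (SD, n = 3) in mock, 49.9 ± 9.58 in EPFL6, 93.9 ± 11.2 in CHX and 84.1 ± 13.6 in CHX plus EPFL6, with single libraries from 40.2 to 106.6 M reads. The 100 most abundant genes took 14.2%, 14.0%, 21.8% and 22.7% of the reads. The deeper CHX libraries and their different composition make the scaling matter for comparisons with and without CHX. Where a group held no reads of a gene, the fold was bounded with 3 reads over the group, which covers counting error only, because the reads carry no molecular identifiers.

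Genes with a value of at least 10 in at least 3 libraries were tested, which left 23225. The log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3, with all 4 groups in a single fit, an intensity trend and robust variance moderation. Adjusted p is Benjamini-Hochberg over the 23225 genes, two-sided, with a threshold of 0.05. The contrasts were EPFL6 against mock, CHX against mock, CHX plus EPFL6 against CHX, CHX plus EPFL6 against EPFL6, and the interaction, which is the EPFL6 change with CHX minus the EPFL6 change without it. The EPFL6 comparisons with and without CHX share no library, though the single fit gives them a common variance. The plan written before the data were examined named edgeR quasi-likelihood tests on counts with TMM scaling. Because the values turned out to be scaled rather than counts, limma became the main test, and edgeR 4.0.16 on the recovered reads was kept as an alternative. It gave 3 genes for EPFL6 against mock, 18317 for CHX against mock, 3269 for CHX plus EPFL6 against CHX, 17977 for CHX plus EPFL6 against EPFL6 and 308 for the interaction.

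The contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are WUS, CLV3, STM and the mutated genes in every comparison. They also include the 10 largest changes per direction among genes past the threshold, with at least 1 CPM on average and no overlap between the compared libraries (chance gives 10% for 3 against 3). In the last 2 contrasts the number was 5 per direction, with no overlap criterion for the interaction. The rule adds up to 4 members of each list, and genes past the threshold in the same direction for EPFL6 with and without CHX. Genes outside the rule are marked as chosen after their values were seen. The 24 lists hold 405 distinct genes, of which ERF105, MYC2 and CRU3 were not analysed here because the file does not list them. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, then with an estimated correlation and with fry.

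The procedure was tested on simulated data with 200 changed genes, 50 of each size. For EPFL6 against mock it recovered 44%, 72%, 92% and 98% of changes of 1.5, 2, 4 and 8-fold, with 14 false calls (8.38% of calls). For CHX plus EPFL6 against CHX the shares were 38%, 64%, 94% and 96%, with 10 false calls (6.41%). CHX against mock gave 36%, 70%, 82% and 90% with 5 false calls, CHX plus EPFL6 against EPFL6 44%, 74%, 84% and 94% with 14, and the interaction 14%, 62%, 78% and 92% with 1. For CHX against mock and CHX plus EPFL6 against EPFL6, every simulated group had the mock means apart from the 200 changed genes. The real comparisons changed 18386 and 18096 genes, so these rates do not carry over to them. A list lowered 1.5-fold in the simulation was called by camera (adjusted p = 3.2e-49), with 0 of the other 23 lists called. The simulated genes varied independently and held no structure beyond the groups. In the real data the estimated correlation within a list reached 0.92 (cytosolic ribosomal proteins). The simulation therefore does not measure how often camera calls lists falsely here. Recovery was measured with 200 planted changes, and fewer changes make the adjusted threshold stricter. In the real EPFL6 against mock comparison 4 genes passed, and 708 had an unadjusted p under 0.05 where 1161 are expected by chance. The recovered shares may be too high for that comparison.

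Alternatives chosen before the values were seen were median-of-ratios scaling in edgeR, library size alone, no filter on low values, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, fitting only the compared groups, a replicate block, leaving out organelle genes, and leaving out each library in turn. Alternatives chosen after the values were seen were TMM scaling in limma, pseudocounts of 0.5 and 8, and thinning the CHX libraries to 40.2 M reads. EdgeR with TMM, planned as the main test, became an alternative only then. Replicate numbers were not taken as pairs, since no label says that they mark a shared day.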

Results

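EPFL6 is a secreted peptide that signals through receptor kinases of the ERECTA family, and cycloheximide (CHX) blocks translation, so the design asks which transcripts answer the peptide when new protein cannot be made. Values below are normalised read counts, given as the mean ± SD of 3 libraries, and log2 fold changes are given ± SE from limma. In mock seedlings the 5 mutated genes still gave reads: 683 ± 94.6 for CLV3, 2980 ± 676 for EPFL2, 85.4 ± 21.3 for EPFL1, 10.3 ± 3.54 for EPFL6 (annotated as CHAL) and 2.59 ± 1.86 for EPFL4 (annotated as CLL2). Reads over a mutated locus do not show whether a working transcript is made. The samples are labelled as seedling shoots, but root markers such as PRP3 (2170 ± 463) and CASP1 (1260 ± 197) were abundant in mock, which goes against a harvest free of roots. The first principal component separated libraries with and without CHX and held 91.2% of the variance. The next held 2.99%.

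EPFL6 alone lowered the stem cell peptide gene CLV3 (AT2G27250, chromosome 2, 11664978 to 11665797) from 683 ± 94.6 to 311 ± 46.5, a log2 fold change of −1.13 ± 0.11 (limma adjusted p = 0.0086). The Mei2-like RNA-binding protein genes MCT2 (−2.06 ± 0.18, adjusted p = 0.0051) and TEL2 (−1.83 ± 0.23, adjusted p = 0.047) were lower as well. MCT2 went from 202 ± 35.3 to 48.1 ± 11, and TEL2 from 347 ± 42.1 to 101 ± 32. The cytochrome P450 gene CYP82C2 had 5 to 17 reads per mock library and 0 in the 3 EPFL6 libraries, at least 10-fold lower over the group (adjusted p = 0.025). CYP82C2 passed in 12 of 25 alternatives (adjusted p 0.0058 to 0.95), and edgeR with TMM gave it an adjusted p of 0.71. These 4 genes, 0 higher and 4 lower, were all that passed in limma. At an unadjusted p under 0.05 there were 708 genes where 1161 are expected by chance. DESeq2 called 31, of which 10 were higher and 21 lower, and edgeR with TMM called 3.

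WUS, the homeobox gene that maintains stem cells (AT2G17950, chromosome 2, 7808871 to 7810811), stood at 379 ± 60.6 in mock and 123 ± 2.27 with EPFL6, and did not pass over all genes (−1.60 ± 0.22, adjusted p = 0.090). The AP2-type genes ESR1, also known as DORNROSCHEN (DRN), and DRNL stood at 62.2 ± 2.51 and 8.11 ± 5.05 in mock and at 161 ± 19.6 and 44.5 ± 1.92 with EPFL6 (adjusted p = 0.34 and 0.14). UFO, chosen after its values were seen, stood at 64.1 ± 6.16 and 149 ± 37.2 (adjusted p = 1), and STM at 1010 ± 40.6 and 961 ± 139 (−0.08 ± 0.22). Adjusted over the list alone, 3 of the 26 shoot meristem regulators were higher with EPFL6 (DRNL, ESR1, UFO) and 2 lower (CLV3, WUS), against 0 and 1 over all genes. Fry gave the list a mixed adjusted p of 1.2e-09 for change in either direction. The same test passed CLE peptide genes (3.1e-06), stomatal lineage (0.00074) and ERECTA-family signalling (0.0071). These lists share members, so the results are not separate signals. The 1 CLE peptide gene past limma is CLV3, also a meristem regulator. TMM, EPF1, EPF2 and ERL1 are in both the stomatal lineage and the ERECTA-family list. The receptor genes ERL1 and ERL2 were at 432 ± 22.6 and 1180 ± 34.9 in mock and 254 ± 54.8 and 805 ± 120 with EPFL6 (adjusted p = 0.45 for both). EPF2, a stomatal peptide gene, stood at 16.1 ± 4.38 and 4.86 ± 0.451 (adjusted p = 0.45).

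Camera placed 3 of the 24 lists past the threshold for EPFL6 alone. They were the stomatal lineage (lower, adjusted p = 0.0012), leaf primordium and polarity regulators (lower, adjusted p = 0.034) and S phase genes (higher, adjusted p = 0.015). None of these lists had a member past limma, and adjusted over the list alone the stomatal lineage had 0 higher and 2 lower and the others 0. The calls were lost, with adjusted p = 0.14, 0.88 and 0.88 with an estimated correlation. ERECTA-family signalling, which shares TMM, EPF1, EPF2 and ERL1 with the stomatal lineage, had 0 members past limma, and 3 lower adjusted over the list alone. Its median of 0.03 and mean of −0.10 differ in sign. The 21 lists not called had camera adjusted p from 0.14 to 0.98.

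Leaving out 1 library ended the call of CLV3 without EPFL6 replicate 2 (adjusted p 0.067; range over 25 alternatives 2.9e-15 to 0.61), of TEL2 without any library other than EPFL6 replicates 1 and 3 (0.066 to 0.26), and of CYP82C2 without mock replicate 2, any EPFL6 replicate, CHX replicate 3 or CHX plus EPFL6 replicate 1 or 2 (0.054 to 0.12). Calls were gained by WUS without CHX plus EPFL6 replicate 1 or 3 (0.019 and 0.015; range 4e-10 to 0.30), DRNL without mock replicate 1 (0.033; range 0.00012 to 0.97) and ESR1 without CHX plus EPFL6 replicate 3 (0.0086; range 2.3e-11 to 0.82). A limma fit of the mock and EPFL6 libraries alone called 0 genes, with 660 at an unadjusted p under 0.05, and a replicate block called 1. Over the 25 alternatives MCT2 passed in 24, CLV3 in 22, CYP82C2 in 12 and TEL2 in 11.

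CHX alone changed 18386 of 23225 genes, 9491 higher and 8895 lower, and 6003 and 3905 of these by at least 2-fold. BHLH92 went from 64.5 ± 36.1 to 66900 ± 24900 (10.06 ± 0.43, adjusted p = 2.8e-09), WRKY30 from 86.7 ± 21.3 to 68100 ± 15200 (9.60 ± 0.22) and RRTF1 from 4.24 ± 1.95 to 4420 ± 2250 (9.67 ± 0.50). FAR8 rose by 9.66, ZAT11 by 8.91, the jasmonate synthesis gene LOX4 by 8.98 and the repressor gene JAZ7 by 7.74. All 35 measured immediate early, wound and elicitor genes rose, with a median log2 fold change of 6.07. The kinase gene MPK3, which acts downstream of ERECTA receptors, rose by 4.74 ± 0.12 to 105000 ± 13500, and the coreceptor gene BAK1 by 2.45. The unfolded protein regulator BZIP60 rose by 6.38, while the chaperone gene BIP1 fell by 2.48.

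The auxin-induced genes BRU6, IAA30 and IAA2 rose by 5.24, 4.86 and 3.00, the auxin transport regulator gene PID by 4.23, and the cytokinin genes CKX4 and ARR7 by 4.30 and 2.39. The auxin synthesis gene YUC2 fell by 4.61, the auxin carrier gene LAX3 by 2.55 and the brassinosteroid synthesis gene ROT3 by 2.71. Large falls came in PER64 (1070 ± 172 to 4.23 ± 2.2, −7.76 ± 0.42, adjusted p = 1.8e-08), PRP1 (−6.85), UCC1 (−6.47) and MYB27 (−6.37). The cytokinesis gene SYP111 fell by 2.40, CYCA1;1 by 3.04, CYCD3;2 by 1.37, the leaf genes GRF1 and AS1 by 2.46 and 2.21, and the ribosomal protein gene RPS15A by 1.42.

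Among meristem genes CHX raised CLV3 to 4710 ± 194 (2.79 ± 0.11, adjusted p = 1.6e-09) and WUS to 1020 ± 126 (1.43 ± 0.22), and lowered STM to 521 ± 70.6 (−0.96 ± 0.22). ESR1 rose by 3.56 to 745 ± 30.8, and the mutated EPFL2 by 2.51 to 16700 ± 1990. EPFL1 rose by 1.28, a call lost with library size alone (adjusted p = 0.067). Of the 26 meristem regulators 10 were higher and 12 lower (10 and 13 adjusted over the list alone), with a median of −0.28 and a mean of 0.06. The list was not past camera (adjusted p = 0.66).

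Camera called 8 lists for CHX against mock. Higher were immediate early genes (35 of 35 higher, adjusted p = 5.6e-13), auxin early response (18 of 23 higher, 0 lower, 0.00018) and jasmonate response and synthesis (17 of 20 higher, 0 lower, 0.0014). Lower were cytosolic ribosomal proteins (20 of 20 lower, 1.6e-06, median −1.16) and G2 and mitosis (17 of 18 lower, 3.6e-05). Also lower were leaf primordium and polarity regulators (6 higher, 14 lower, 0.027), nuclear photosynthesis genes (14 of 22 lower, 0.029) and root markers (2 higher, 9 lower, 0.048). Adjusted over the list alone the counts were equal except for photosynthesis, with 13 lower. All 8 calls were lost, with adjusted p = 0.51 to 0.80 with an estimated correlation.

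The other 16 lists had camera adjusted p from 0.054 to 0.97 after CHX. ERECTA-family signalling had 15 higher and 3 lower, cytokinin response 11 and 4, seed storage markers 3 and 0 of 4, nonsense-mediated decay targets 7 and 5, vascular markers 4 and 1, and S phase 5 and 4. Stomatal lineage had 4 higher and 4 lower, auxin synthesis and transport 5 and 9, ribosome biogenesis 3 and 8, heat and unfolded protein response 4 and 6, and epidermis markers 2 and 6. Brassinosteroid genes had 2 and 5, CLE peptide genes 4 and 4, D-type cyclins 2 and 4, and clock genes 3 and 3. Adjusted over the list alone these 15 counts were equal except for clock genes, with 2 and 2. Scaling by library size alone shifted the median log2 fold change of all genes from 0.02 to −0.74, so that 72.5% of changed genes were lower against 48.4%, and directions here are relative to the median gene.

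With CHX present, EPFL6 lowered many shoot meristem regulators. WUS went from 1020 ± 126 to 95.7 ± 34 (−3.45 ± 0.22, limma adjusted p = 1.1e-05), CLV3 from 4710 ± 194 to 853 ± 13 (−2.46 ± 0.11, adjusted p = 2.3e-06) and STM, which keeps meristem cells undifferentiated, from 521 ± 70.6 to 103 ± 36.2 (−2.38 ± 0.22, adjusted p = 0.00019). Among named genes the largest fall was in ESR1, from 745 ± 30.8 to 26.5 ± 10.4 (−4.84 ± 0.25, adjusted p = 3.6e-06), and UFO went from 79 ± 17.7 to 2.71 ± 2.17 (−4.56 ± 0.35, adjusted p = 5.5e-05; −5 without CHX plus EPFL6 replicate 3 and −3.02 with a pseudocount of 8). The homeobox gene BLH8, also known as POUNDFOOLISH, fell by 2.59 from 430 ± 47.5 to 70.5 ± 6.56. Across the genome 3140 genes changed, 1367 higher and 1773 lower, but 20 rose and 521 fell by at least 2-fold, and 0 rose and 40 fell by at least 8-fold.

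**Figure D1:**
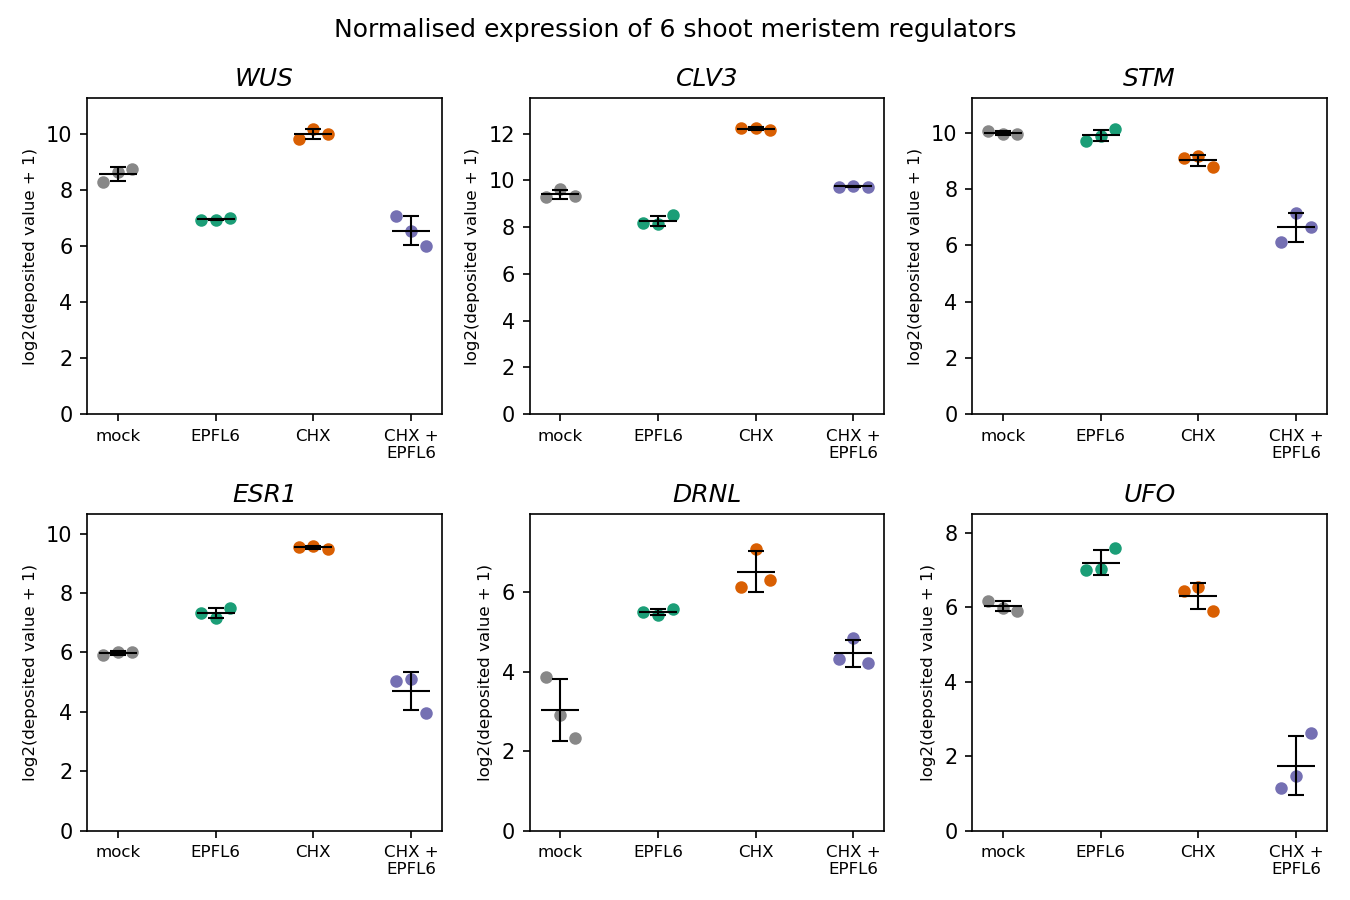
Log2 of the normalised read count plus 1 in each library (dots) with group mean ± SD (n = 3) for 6 meristem genes in mock, EPFL6, CHX and CHX plus EPFL6 samples. The mean of WUS is 1020 with CHX and 95.7 with CHX plus EPFL6, and that of ESR1 745 and 26.5.

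Of the 26 meristem regulators 14 were lower with CHX plus EPFL6 than with CHX and 0 higher (16 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.1e-10). Beside the genes above these were, named after their values were seen, the boundary genes CUC1 (−1.46) and CUC2 (−1.07, adjusted p = 0.042), the KNOX genes KNAT1 (−0.82), KNAT2 (−0.81) and KNAT6 (−0.46), the partners ATH1 (−0.67, adjusted p = 0.039) and RPL (−0.75), and DRNL (−2.05). In 11 of the 14 the mean with CHX plus EPFL6 was below the mock mean, and over all 1773 lowered genes this held for 872. The Mei2-like genes MCT1 (193 ± 22.5 to 7.1 ± 3.47, −4.69 ± 0.30), TEL2 (−3.62 ± 0.23) and MCT2 (−3.24 ± 0.18) fell as well.

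The receptor gene ERL2 went from 454 ± 18.3 to 100 ± 12.1 (−2.17 ± 0.12, adjusted p = 4.7e-06) and ERL1 from 350 ± 67.5 to 146 ± 4.98 (−1.24 ± 0.16). ER stood at 889 ± 182 and 562 ± 8 (adjusted p = 0.018, and 0.051 and 0.062 without CHX plus EPFL6 replicates 1 and 2). Among leaf primordium genes ANT, which drives organ growth, fell by 1.64, AIL7 went from 1130 ± 97.1 to 564 ± 14.3, PHB fell by 0.52 and ATHB-15 by 0.51. The auxin synthesis genes YUC4 and TAA1 fell by 2.39 and 1.07, and the auxin uptake gene AUX1 by 0.63. The cytokinin genes CKX3, ARR15 and RR16 fell by 1.86, 1.53 and 0.77, the auxin response gene IAA29 by 1.13, the brassinosteroid breakdown gene BAS1 by 1.03 and the mitotic kinase gene CDKB2;1 by 0.71.

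Among genes that rose, GLIP1, a secreted lipase gene, went from 928 ± 106 to 3220 ± 744 (1.77 ± 0.29, adjusted p = 0.0052), AT5G39030 from 378 ± 51.4 to 828 ± 113 (1.13), AT5G03490 from 1780 ± 455 to 3780 ± 20.6 (1.12) and AT5G12420 from 747 ± 114 to 1610 ± 247 (1.11). CYP82C2 went from 101 ± 34.5 to 282 ± 76.6 (1.5 ± 0.38, adjusted p = 0.030). That call was lost (0.057 to 0.10) on leaving out any single library with CHX other than CHX replicate 1. Of the mutated ligand genes, EPFL1, EPFL2 and the endogenous EPFL6 gene did not pass with CHX plus EPFL6 against CHX (adjusted p = 0.42, 0.42 and 0.46), and EPFL4 was too low to test.

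**Figure D2:**
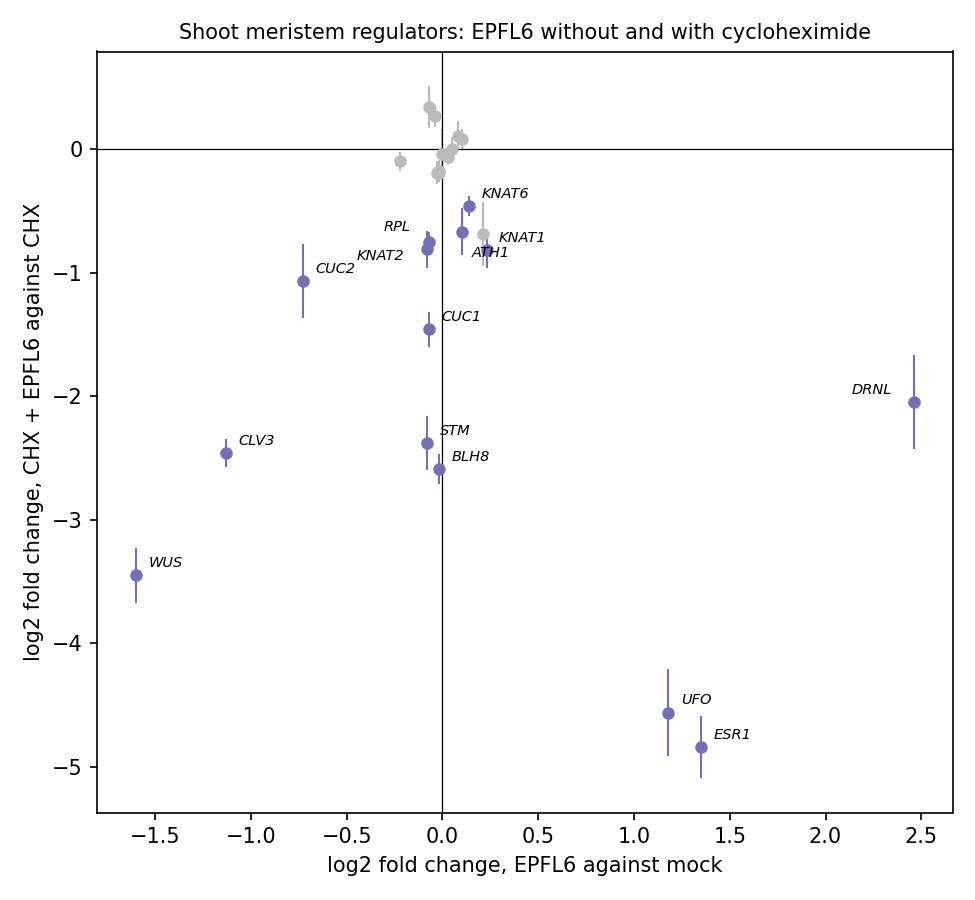
Log2 fold change with EPFL6 against mock (x axis) and with CHX plus EPFL6 against CHX (y axis) for the 26 shoot meristem regulators, with bars of 1 SE on the y value and purple dots for the 14 past limma on the y axis. All 14 lie below 0 on the y axis, while on the x axis DRNL is at 2.46 and WUS at −1.60.

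Camera called 16 of 24 lists for CHX plus EPFL6 against CHX, and 3 of these calls held with an estimated correlation (adjusted p = 0.025 for each). They were the meristem regulators, auxin synthesis and transport (8 of 17 lower, 0 higher, 10 lower adjusted over the list alone, 1.6e-05) and cytokinin response and breakdown (7 of 18 lower, 0 higher, 7 adjusted over the list alone, 4e-04). Lower with the preset but not with an estimated correlation were leaf primordium and polarity (9 lower, 0.00063), ERECTA-family signalling (5 lower, 0.016), stomatal lineage (3 lower, 0.0072), auxin early response (7 lower, 0.002) and immediate early genes (6 lower, 0.00041). Jasmonate genes (4 lower, 1.5e-05), S phase (5 lower, 0.00021), G2 and mitosis (4 lower, 0.002), D-type cyclins (3 lower, 0.012) and root markers (2 lower, 0.025) were lower too, and 0 members of these 10 lists were higher. Cytosolic ribosomal proteins (0 past limma, 5.7e-05), ribosome biogenesis (2 higher, 0.0004) and photosynthesis genes (0 past limma, 0.016) were higher. These 13 had adjusted p = 0.17 to 0.57 with an estimated correlation. Fry called 9 of the 16 lists in the same direction as camera.

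Adjusted over the list alone, the lower counts for CHX plus EPFL6 against CHX were 12 for leaf primordium (and 2 higher), 5 for ERECTA-family signalling, 6 for stomatal lineage (and 1 higher), 9 for auxin early response, 8 for immediate early genes, 6 for jasmonate, 10 for S phase, 6 for G2 and mitosis, 3 for D-type cyclins and 3 for root markers. The higher counts were 0 for ribosomal proteins, 2 for ribosome biogenesis and 0 for photosynthesis. The jasmonate members JAZ7 and OPR3 were lower by −1.68 and −1.89, calls lost (0.052 to 0.10) without CHX replicate 2 or 3 or CHX plus EPFL6 replicate 2 or 3. Not past camera were brassinosteroid genes (0.28), CLE peptide genes (0.082), nonsense-mediated decay targets (0.30), heat and unfolded protein response (0.62), clock genes (0.25), seed storage markers (0.21), epidermis markers (0.51) and vascular markers (0.21).

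**Figure D3:**
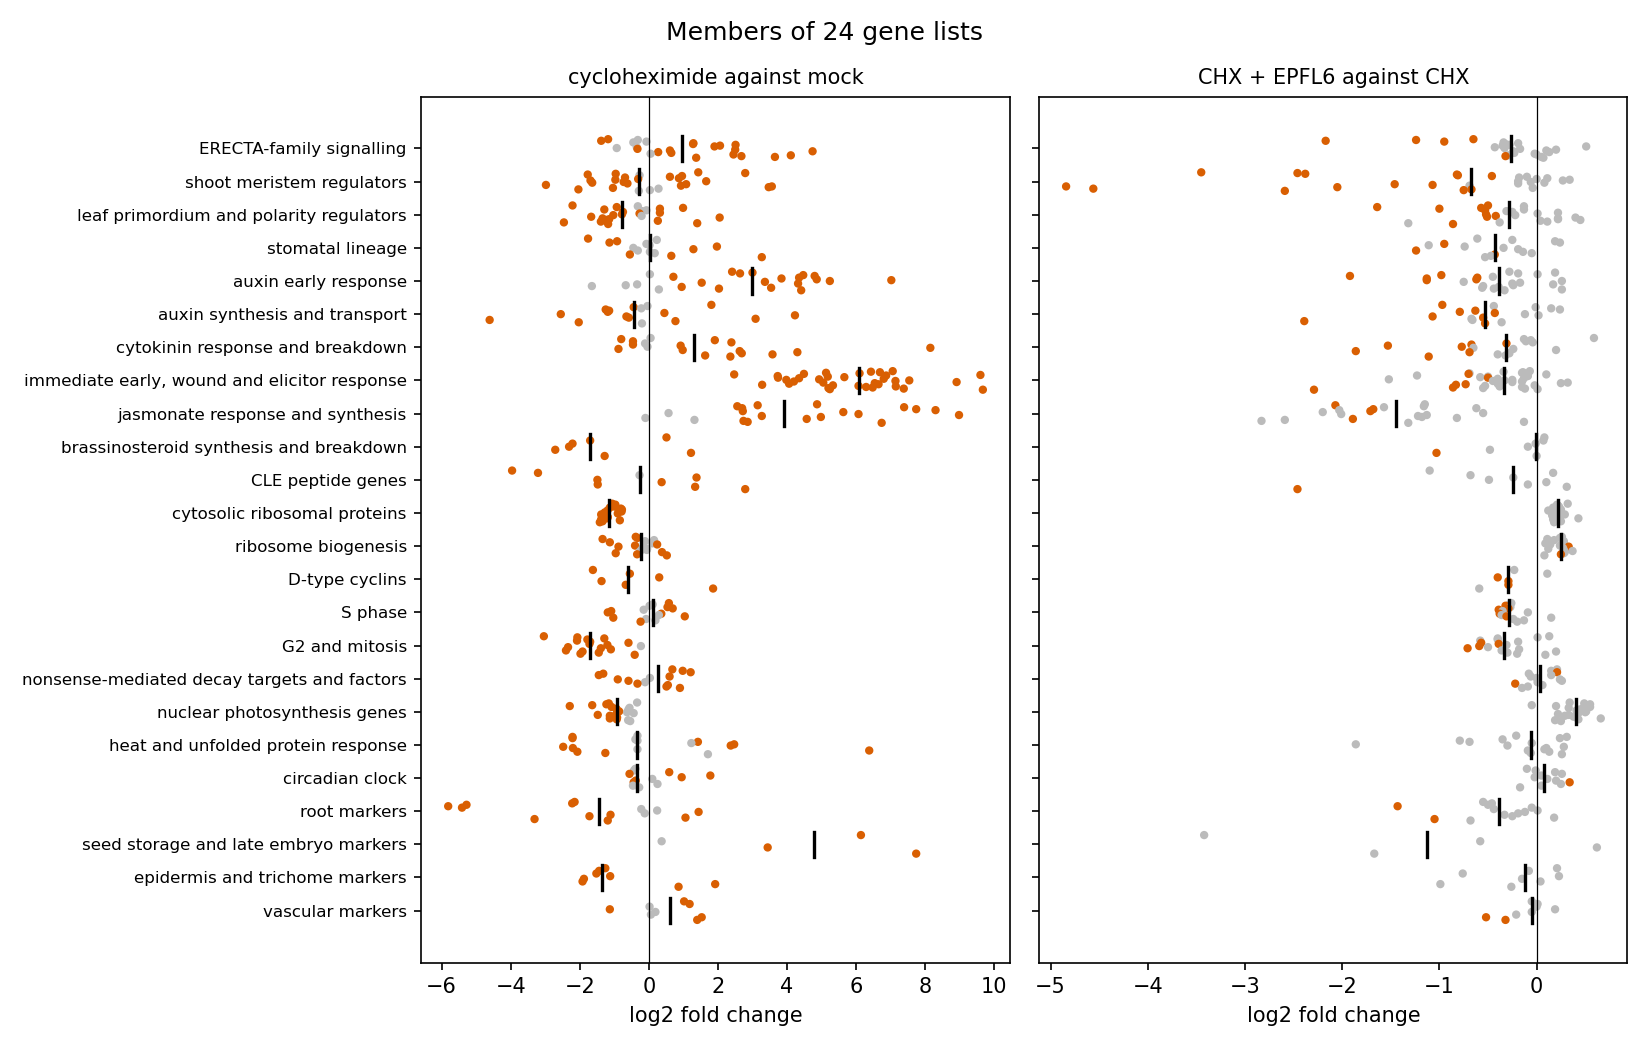
Log2 fold change of each measured member (dots) of the 24 gene lists for CHX against mock (left) and CHX plus EPFL6 against CHX (right), orange where past limma, with the list median as a black line. The median of the immediate early genes is 6.07 on the left and −0.34 on the right, and that of the meristem regulators −0.28 and −0.68.

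The number of genes changed by EPFL6 with CHX moved with the libraries. It was 3972, 1663 and 1018 without CHX replicates 1, 2 and 3, and 2337, 1403 and 1219 without CHX plus EPFL6 replicates 1, 2 and 3. WUS, CLV3, STM, ESR1, UFO, MCT2 and TEL2 were lower and past the threshold in 25 of 25 alternatives.

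The response to EPFL6 differed with and without CHX for 349 genes, 85 with a higher and 264 with a lower interaction term. ESR1 had −6.20 ± 0.36 (adjusted p = 7.3e-05), since it stood higher with EPFL6 alone and fell with CHX present. UFO had −5.74 ± 0.50 (adjusted p = 0.00068), with −6.18 to −4.12 over 24 alternatives. DRNL, chosen after its values were seen, had −4.51 (0.0031) and CYP78A5, a P450 gene of organ growth, −3.91 ± 0.32 (0.00043). CYP78A5 stood at 905 ± 112, 1260 ± 322, 493 ± 70.1 and 44.8 ± 12.5 in mock, EPFL6, CHX and CHX plus EPFL6. For CLV3 (−1.33 ± 0.16, adjusted p = 0.0031) and WUS (−1.85 ± 0.31, adjusted p = 0.023) both EPFL6 changes were negative and the one with CHX was larger. STM (−2.30 ± 0.31, adjusted p = 0.0069) and BLH8 (−2.57 ± 0.18, adjusted p = 0.00014) changed by −0.08 and −0.02 with EPFL6 alone. MCT1 had −3.72 and ERL2 −1.61.

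Among named genes CYP82C2 had the largest positive fitted value (4.86 ± 0.54, adjusted p = 0.0023), which depends on the pseudocount because the EPFL6 group held 0 reads. The methyltransferase gene IGMT1 (1.57 ± 0.20, adjusted p = 0.0049) stood at 1080 ± 168 and 543 ± 81.4 without CHX and at 18900 ± 468 and 28500 ± 4130 with it, and PLA2A had 1.33 ± 0.21 (0.017). Of the 26 meristem regulators 11 had a lower interaction and 0 a higher (13 lower adjusted over the list alone; camera adjusted p = 3.6e-10). Camera called 16 lists, and 3 calls held with an estimated correlation (adjusted p = 0.027 each). They were the meristem regulators, auxin synthesis and transport (8.2e-05; 3 lower, 7 adjusted over the list alone) and cytokinin response (0.00066; 0 past limma, 8 lower adjusted over the list alone). The other 13 had adjusted p = 0.38 to 0.58 with an estimated correlation.

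The interaction count was 1518 with DESeq2 (558 higher, 960 lower), 187 with a replicate block and 208 with library size scaling. It was 86, 154 and 173 without mock replicates 1, 2 and 3, 201, 125 and 118 without EPFL6 replicates 1, 2 and 3, 954, 149 and 136 without CHX replicates 1, 2 and 3, and 365, 122 and 114 without CHX plus EPFL6 replicates 1, 2 and 3. The call for WUS was lost (adjusted p 0.057 to 0.065; range over 24 alternatives 1.6e-06 to 0.065) without mock replicate 1, EPFL6 replicate 2 or 3, CHX replicate 2 or 3, or CHX plus EPFL6 replicate 2.

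Against EPFL6 alone, CHX plus EPFL6 changed 18096 genes, 9340 higher and 8756 lower. STM fell from 961 ± 139 to 103 ± 36.2 (−3.27 ± 0.22, adjusted p = 9.7e-08), with KNAT1 (−2.82), BLH8 (−2.85) and ERL2 (−2.99) lower too, while CLV3 rose from 311 ± 46.5 to 853 ± 13 (1.46 ± 0.11). WUS stood at 123 ± 2.27 and 95.7 ± 34 (−0.42, adjusted p = 0.10), but was lower with library size scaling (−1.15, 0.00043) and without CHX plus EPFL6 replicate 1 (−0.68, 0.0071; range over 25 alternatives 0.00043 to 0.44). The root endodermis gene CASP1 (−7.46), PER64 (−7.70) and PRP1 (−7.62) were lower, and AT1G48980 and sks8 rose by 10.08 and 9.94. Of the meristem regulators 5 were higher and 18 lower, with equal counts adjusted over the list alone (camera adjusted p = 0.0069). Camera called 10 lists, all lost with adjusted p = 0.34 to 0.68 with an estimated correlation. Scaling by library size alone shifted the median of all genes from 0.03 to −0.71 and gave 5283 higher and 14550 lower.

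CLV3, MCT2 and TEL2 were lower with EPFL6 both without and with CHX. These are 3 of the 4 genes lower without CHX, where 0.31 would be shared by chance (Fisher's exact test, two-sided, p = 0.0017), and 0 of 0 higher genes were shared. The single fit gives both comparisons a common variance, so these calls are not independent, and 0 genes were shared with only the compared groups in each limma fit and 1 with a replicate block. The fourth, CYP82C2, rose with CHX. Of the 21 genes that DESeq2 called lower with EPFL6 alone, 15 were called lower by limma with CHX present, among them WUS, MCT1, ERL1, ERL2 and AGO5, and 2 higher, CYP82C2 and IGMT1 (the DESeq2 genes were chosen after their values were seen). Of the 10 that DESeq2 called higher, 5 were called lower by limma with CHX present, ESR1, DRNL, UFO, SAP and AT5G38700, and 0 higher. With DESeq2 in both comparisons 16 genes were called in the same direction and 8 in opposite directions. Across all 23225 genes the EPFL6 changes without and with CHX had a Pearson r of 0.09 and a Spearman rho of 0.01, and genes are not independent replicates.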

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

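The tests of root markers, of the share of meristem cells and of genes with a CHX response of at least 8-fold were chosen only after the result was seen, and thinning is an alternative added after the values were seen.

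A difference between the EPFL6 changes without and with CHX, tested by the interaction term in limma, picked out 349 genes. Among them are ESR1 (−6.20), UFO (−5.74), AT2G06045 (−5.63), CYP78A5 (−3.91), MCT1 (−3.72), BLH8 (−2.57), STM (−2.30), WUS (−1.85), ERL2 (−1.61) and CLV3 (−1.33) with negative terms, and CYP82C2 (4.86), IGMT1 (1.57), AT1G26410 (1.35), PLA2A (1.33) and AT4G08780 (1.25) with positive ones. AT2G06045 had 0 reads in mock, so its fitted value depends on the pseudocount. Over 24 alternatives the term of UFO ran from −6.18 to −4.12 and that of CYP82C2 from 2.57 to 7.87. Of 100 splits of the libraries within the groups with and without CHX, 2 gave as many genes, the real one included, but this share does not decide the role of chance. The 93 splits that mixed the libraries with CHX gave at most 2 genes. Among the 7 that kept them as labelled, which are too few for a share under 0.05, the real split gave 349 and the 6 others 186 to 942. The highest put mock replicates 1 and 3 with EPFL6 replicate 3 against mock replicate 2 with EPFL6 replicates 1 and 2, a division also seen in the principal components. The count therefore follows the change with CHX, and a structure of the 6 libraries without CHX, not named by the labels, bears on it.

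EPFL6 changed 3140 genes with CHX and 4 without. Deeper sequencing of the CHX libraries is argued against, since 2860 genes passed after thinning them to 40.2 M reads. So is a larger spread between the libraries without CHX, since the main fit gives both comparisons the same spread per gene. With each gene's spread taken from mock and EPFL6 libraries alone 2570 genes passed, and 1431 with that of the CHX and CHX plus EPFL6 libraries. The median SD of the log2 values was 0.147 and 0.15. A weaker CHX response in the libraries that also had EPFL6 would turn the called genes against their CHX response, but 55.1% of them moved that way, as did 55.06% of all tested genes, which argues against it as the whole cause. For part of the genes the values go with it: 78.4% of the 333 called genes with a CHX response of at least 8-fold moved against that response (52.3% of the other 2807). Among all tested genes the shares were 62.4% of 2726 with at least 8-fold and 54.1% of the other 20499. All 20 jasmonate genes and 31 of 35 immediate early genes were negative. The first principal component was 144.7 to 152.5 in CHX plus EPFL6 and 154.6 to 167.9 in CHX libraries. The next was −45.4 to −15.6 in CHX plus EPFL6 and 17.7 to 53.5 in CHX libraries. It also divides the libraries without CHX in a way no label names. Whether such a structure adds to the 3140 genes was not tested. A hypothesis that stays open is biological: blocked translation may remove newly made proteins that limit the answer to EPFL6, which was not tested, and neither was the time of exposure.

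Meristem genes were lower with EPFL6 in the presence of CHX, 14 of 26. After subtraction of the trend of the EPFL6 change on the CHX response over all genes, the median of these 14 went from −1.76 to −1.74, so 99.1% was kept, and 12 of the 14 stayed past the test. The trend over all genes was shallow (linear slope −0.034), so subtracting it takes little from most sets and cannot decide the question for these genes. Of the 14, 6 were past limma as higher with CHX against mock and 4 as lower. Those 4 fell further with EPFL6, which argues against a weaker CHX response as their whole cause. A smaller share of meristem cells would lower the members alike only if all were confined to the meristem. The SD of log2 fold change over the list was 1.46, with ESR1 at −4.84, WUS at −3.45 and CLV1 at −0.10 ± 0.08 (SE). Which members are confined to the meristem was not measured, so this spread cannot decide the question. A smaller share of meristem cells and a loss of particular meristem cells both stay open. That WUS, STM and ESR1 may answer EPFL6 without new protein synthesis is a hypothesis that was not tested, since the data hold no measure of how far translation was blocked.

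Root markers were lower with CHX against mock (2 higher, 9 lower of 14), with CASP1 at 1260 ± 197 and 21.9 ± 6.22, though the list call was lost (adjusted p = 0.60 with an estimated correlation). The labels name shoots, yet root markers such as CASP1 were abundant in mock, which goes against a harvest free of roots. A smaller share of root tissue in the CHX samples, acting alone, would lower all of them alike if all were confined to roots. The SD of their log2 fold changes was 2.37, and the 2 that rose are not accounted for by it alone. After CHX the SD of other lists ran from 0.22 (cytosolic ribosomal proteins) to 3.23 (seed storage markers), with 2.39 for heat and unfolded protein response. Such a spread can thus come with the CHX response itself, and it cannot decide whether the share of root tissue fell. A smaller share of root tissue stays open. A change of transcription or RNA stability in root cells stays open too and was not tested.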

How the results depend on the processing

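Tests with TMM in limma, other pseudocounts and thinning were chosen after the values were seen. EdgeR with TMM was the planned main test and became an alternative at that point. Of the named genes past the threshold, 114 of 117 kept direction and call in every alternative for CHX against mock, 100 of 107 for CHX plus EPFL6 against EPFL6, 33 of 75 for CHX plus EPFL6 against CHX (12 of the 42 others lost it only on leaving out a library), 13 of 22 for the interaction and 0 of 4 for EPFL6 against mock. Counts for CHX against mock stayed between 17549 and 18363 on leaving out 1 library, and for CHX plus EPFL6 against EPFL6 between 17250 and 18250. With DESeq2 EPFL6 alone changed 31 genes and the interaction 1518. Both EPFL6 comparisons shared 16 genes in the same direction, and 8 were called in opposite directions. With only the compared groups in the fit, EPFL6 alone changed 0 genes in limma (660 at an unadjusted p under 0.05; fits of all 4 groups gave 31 in DESeq2 and 3 in edgeR), EPFL6 with CHX 1505, and 0 were shared; these fits estimate the spread from fewer libraries. With a replicate block the values were 1 for EPFL6 alone, where the calls of CLV3, TEL2 and CYP82C2 ended, 187 for the interaction and 1 shared. Whether replicate numbers mark a shared factor stays open: deviations from the group means correlated best with their own number in 9 of 18 pairs, where 6 would by chance (r −0.22 to 0.42). Thinning gave 2 for EPFL6 alone, and library size scaling 208 for the interaction. Leaving out 1 library gave 1 to 5 genes for EPFL6 alone (1 without EPFL6 replicate 2, 2 without CHX replicate 3 or CHX plus EPFL6 replicate 2), 1018 to 3972 for EPFL6 with CHX, 86 to 954 for the interaction, 1 to 4 shared genes (1 without EPFL6 replicate 2) and r of −0.02 to 0.21 (−0.02 without mock replicate 3 or EPFL6 replicate 1, 0.21 without mock replicate 2 or EPFL6 replicate 3). With an estimated correlation the lists called were 0 for EPFL6 alone, 0 for CHX, 3 for EPFL6 with CHX, 0 for CHX plus EPFL6 against EPFL6 and 3 for the interaction; fry called 0, 19, 11, 20 and 6, and library size scaling left 6 for CHX plus EPFL6 against EPFL6. Library size scaling also turned MCM6 with CHX (−0.06) and NRPA2 (−0.09) and PCL1 (−0.22) with CHX plus EPFL6 against EPFL6, through its shift of all genes. Elsewhere the cause was not tested. Depth limits genes such as EPFL4, with means of 2.3 to 6.81.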

Other observations

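The sets of the largest 40 and 100 and the most significant 100 lowered and raised genes, the Mei2-like family and the chromosome 4 cluster were chosen only after the result was seen.

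A hypothesis was that genes lowered by EPFL6 with CHX are also lower with EPFL6 alone, in libraries the comparison does not share. Over all 1773 genes camera gave p = 0.51 (0.85 with an estimated correlation) with a median of 0 and 50.1% of the same sign, and over the 1367 raised genes p = 0.61. The bound written beforehand read such a p as no movement, which was wrong, since it does not show that a set stayed still, and the hypothesis is left open. The 40 largest falls gave p = 0.00053 (0.047 with an estimated correlation, median −0.13) and the 100 largest p = 5.1e-06 (0.057 with an estimated correlation, median −0.11, 61% of the same sign). The 40 largest rises gave p = 0.61 (0.79 with an estimated correlation, median 0, 42.5% of the same sign) and the 100 largest p = 0.79 (0.93 with an estimated correlation, median 0.01). Of the 100 most significant falls 73% were negative with EPFL6 alone (median −0.1), and of the 100 most significant rises 47% were positive.

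For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real count was 18386 for CHX against mock, 3140 for CHX plus EPFL6 against CHX and 18096 for CHX plus EPFL6 against EPFL6, each with 0 as the highest other count (1 of 10 splits as large, the real one). For EPFL6 against mock the real count was 4 and the highest other 47 (2 of 10 splits as large). That split set mock replicates 1 and 3 and EPFL6 replicate 3 against mock replicate 2 and EPFL6 replicates 1 and 2. It follows the next principal component, at 9.5, 20.3 and 19.6 against −19.7, −15.2 and −6.9, which points to a structure of the samples that the labels do not name. The same component was at 25.2, 17.7 and 53.5 in CHX and at −15.6, −43.1 and −45.4 in CHX plus EPFL6 libraries. The unnamed division and the EPFL6 change with CHX thus lie along a shared component.

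Of 9 Mei2-like genes MCT1, TEL2, MCT2 and ML2 (−0.46 ± 0.09, adjusted p = 0.012) were lower with EPFL6 in the presence of CHX and ML5 was higher (0.36 ± 0.09, adjusted p = 0.026), while TEL1 (−1.11 ± 0.33, adjusted p = 0.051), ML1, ML3 and ML4 did not pass, so members went both ways. The 6 tested genes of a cluster of neighbouring B3-domain genes on chromosome 4 (15317499 to 15333553) were lower with EPFL6 in the presence of CHX. Other genes of the cluster were too low to test or not listed. REM1 (AT4G31610) had −2.81, AT4G31615 −2.82, AT4G31620 −3.11, AT4G31630 −3.22, AT4G31640 −3.48 and AT4G31650 −0.48 (adjusted p = 0.047, and 0.062 with library size scaling). With EPFL6 alone they lay between −0.25 and 0.09 (adjusted p = 1 for each). AT4G31610 and AT4G31615 overlap, so reads can be shared between them.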
